A study of Mus musculus with 8 samples.

How the data were processed

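RNA from 8 samples of mouse B-lymphoid cells, with a strain label of SW129/C57BL/6J, was profiled on Affymetrix MoGene 1.0 ST arrays, which carry probes along the length of each transcript. Per the labels' protocols, RNA was extracted with Trizol and purified on a Qiagen column. A 200 ng amount was then reverse transcribed with random hexamers, amplified and end-labelled with biotin with the Affymetrix whole-transcript sense target kit. Per the submitters' processing notes the tool was MAS5, a method built on paired mismatch probes, which this array type lacks, so how the values were made is uncertain; its version and settings, the probe summarization and the annotation version are not given in the sources used here. The authors deposited log2 values, 1 column per sample, for 34760 probe sets. The log base and scaling were read from the values: after conversion to the linear scale, the mean over all probe sets with 2% trimmed was 500 on each array. That scaling fixes the mean of each array and not its distribution, and the medians still differed between arrays. A scaling of this kind leaves differences between arrays that depend on signal level. No detection calls were used, so no signal is given as a bound, and the size of a difference near the bottom of the scale is uncertain.

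Probe sets were named through the platform annotation supplied with the series: 21640 had 1 gene symbol, 1321 several and 11799 none. Entrez identifiers of 21553 of the single-symbol probe sets were found in a gene table of the mouse assembly GRCm38.p6, and 0 symbols needed updating. Because the build behind the array annotation is not given in the sources used here, that table served only for names and for the order of neighbouring genes, and no coordinates are printed. For each gene the single-symbol probe set with the highest mean over the 8 arrays was used, which gave 19937 genes; 954 of them had more than 1 probe set. Probe sets with several symbols or none were left out of the main test.

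Groups were taken from the genotype label. Replicates were numbered in order of deposit within a genotype, because the labels carry no replicate number. Knockout replicates 1 and 2 and wild-type replicates 1 and 2 have titles of the RO scheme, and replicates 3 and 4 of each have D/F titles. The labels do not call these schemes batches. The log2 values were used as deposited, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) with genotype and naming scheme as terms, which left 5 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes at a threshold of 0.05. Jun and Cdk6 were also compared by a 2-sided exact permutation test over the 70 assignments of 4 and 4 arrays, without the naming scheme. The interaction of genotype and naming scheme, the difference between naming schemes, and fits within each scheme used the same functions. Each SE is that of the limma coefficient after moderation.

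The 27 gene lists held 622 genes, of which 563 were measured by a single-symbol probe set. They covered the AP-1 family and described AP-1 targets, G1 control, DNA replication, mitosis, histones, DNA methylation, the early B-cell programme, mature B and plasma cells, and markers of myeloid, T and NK, erythroid and megakaryocyte, stem and stromal cells. Further lists covered immediate-early, JAK-STAT5, interferon, apoptosis, p53, Myc, cholesterol, glycolysis and hypoxia, stress response, oxidative phosphorylation, adhesion, sex-linked and MHC genes. The 26 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. List p-values were adjusted over the 26 lists.

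The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule named Jun and Cdk6. It then took up to 12 genes per direction of largest change that passed the adjustment and had the same sign in both naming schemes, or, where fewer passed, those and the genes of smallest p up to 6 in all, given as values that did not pass. It left out predicted, olfactory and vomeronasal receptor, small RNA and accession-type symbols. Last, it took up to 4 members of smallest p per list. In all it named 116 genes. The alternatives were a fit without the naming scheme, quantile normalization, centring on array medians, 2 filters on dim genes, every probe set, the mean of a gene's probe sets, eBayes without trend or with robust priors, the naming scheme as a random block, array weights, each scheme alone and each array left out. Single named genes other than Jun, Cdk6 and Pja1 were refitted without the naming scheme, after both rescalings, without trend and with each array left out. Pseudocount alternatives had been foreseen for linear values and do not apply to log2 values. A fit without the 2 arrays of highest median, a fit with the Xist level as a covariate, random lists matched on signal and rescaled fits of 1 split of the arrays were added after the data were seen.

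The limma step was tested on simulated data with independent Gaussian noise, 19937 genes and 200 planted changes in 20 simulations of the genotype comparison. It recovered 80.5% of planted log2 changes of 1, 98.2% of 1.5, 99.9% of 2 and 100% of 3, and 6.4% of its calls were false. These shares hold for many changes planted at once and noise independent between genes. On the real arrays Jun, at -2.38, and Cdk6, at -2.48, did not pass the adjustment over all genes. A small number of calls therefore does not exclude other large changes. With nothing planted, 8 of 20 simulations made at least 1 call. The list test called 20 of 20 moved lists and 0 of 20 unmoved lists of 30 genes, in simulations without correlation between genes.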

Results

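Transcript levels were measured in 8 samples of mouse B-lymphoid cells, 4 labelled as c-jun knockout and 4 as wild type, on 1 Affymetrix MoGene 1.0 ST array per sample. The series concerns lymphoid leukemia driven by BCR-ABL, a fusion tyrosine kinase, and a role of the AP-1 transcription factor c-JUN in methylation near the start of Cdk6. The sample labels do not say whether the cells carried BCR-ABL. They also do not say whether samples of 1 genotype came from separate cultures or animals. The sex-linked transcripts described below argue against 1 source for all samples of a genotype, but some samples may still be repeats of the same source. The p-values therefore measure the spread between these samples, which may be partly technical. The sample titles follow 2 naming schemes, RO and D/F, with 2 knockout and 2 wild-type samples in each. The values were log2 signals with array medians between 6.93 (knockout replicate 2) and 7.42 (wild type replicate 3), and the number of arrays limits the precision. The Pearson correlation of the log2 signals between arrays ran from 0.951 to 0.979 in 28 pairs. It had a median of 0.970 in the 4 pairs that shared genotype and naming scheme and 0.972 in the 8 pairs that shared neither.

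The first question was whether the targeted gene was low in the samples labelled knockout. Jun (probe set 10514466), which encodes c-JUN, was at 6.86 ± 0.27 (SD, n = 4) on the log2 scale in knockout samples and at 9.25 ± 0.87 (SD, n = 4) in wild-type samples. The signals were 6.99, 6.46, 7.02 and 6.97 in knockout replicates 1 to 4 and 8.82, 8.84, 10.55 and 8.77 in wild-type replicates 1 to 4. All 4 knockout samples lay below all 4 wild-type samples, a 5.22-fold lower level (log2 difference -2.38, SE 0.32). Each knockout signal lay below the median signal of its own array, so the size of the fall is uncertain. A 2-sided exact permutation test gave p = 0.0286, the smallest value the 70 assignments of 4 and 4 arrays allow. Jun ranked 2 among all genes by limma p (1.06e-05), and its adjusted p over all genes was 0.106. The difference was -2.10 in the RO samples and -2.67 in the D/F samples. The labels do not give the part of the gene that was deleted, so the place of the probes relative to it is not known.

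The second question was the level of Cdk6, the cyclin-dependent kinase of G1 that the series is about. Cdk6 (probe set 10519324) was at 8.81 ± 1.48 (SD, n = 4) in knockout samples and at 11.30 ± 0.29 (SD, n = 4) in wild-type samples. The 5.59-fold lower level (log2 difference -2.48, SE 0.56) was present in all 4 knockout samples, whose signals were 9.69, 8.66, 10.11 and 6.79, against 11.11, 11.002, 11.50 and 11.58 in wild-type samples. The 2-sided exact permutation test again gave the smallest possible p, 0.0286. With the limma p-values of Jun and Cdk6 adjusted for these 2 prespecified genes alone, Cdk6 had 0.000875 and Jun 2.13e-05. Over all genes Cdk6 ranked 11 and its adjusted p was 0.878. The difference was -1.88 in the RO samples and -3.09 in the D/F samples, and it was -1.70 without knockout replicate 4, the sample with the lowest Cdk6 signal.

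**Figure D1:**
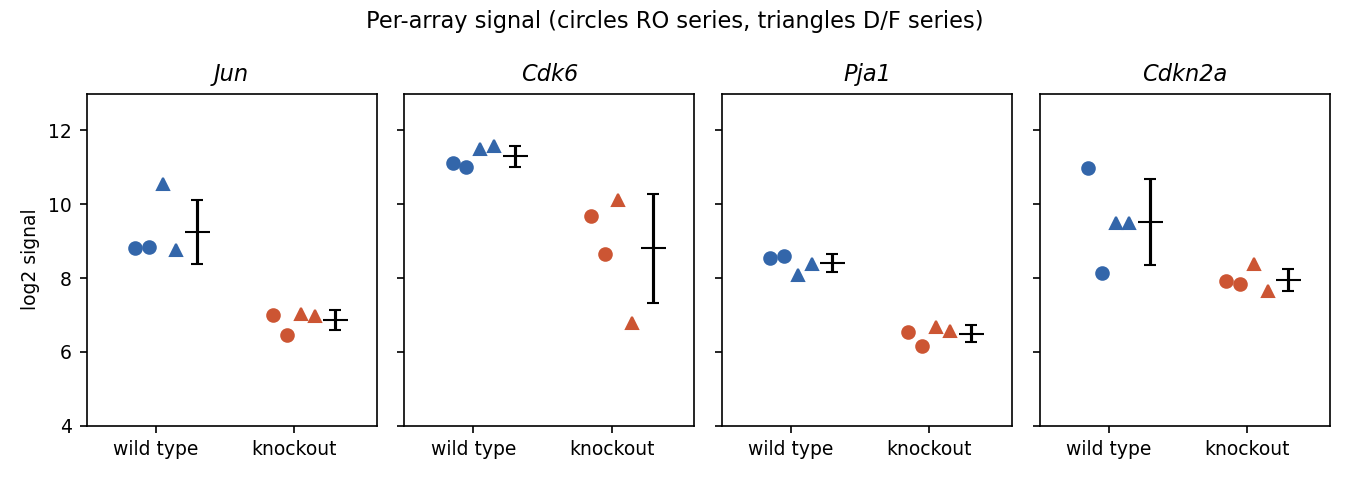
Log2 signal of Jun, Cdk6, Pja1 and Cdkn2a on each array (vertical axis), by genotype (horizontal axis); circles are RO samples, triangles D/F samples, and each bar shows the mean ± SD of 4 samples. All 4 knockout samples lie below all 4 wild-type samples for Jun, Cdk6 and Pja1; for Cdkn2a wild type replicate 2, at 8.13, lies within the knockout samples.

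Among all genes, 1 was lower in knockout samples after Benjamini-Hochberg adjustment of the limma p-values, and 0 were higher. The gene was Pja1 (probe set 10605919), which encodes the E3 ubiquitin ligase praja 1 and lies on chromosome X. It was at 6.49 ± 0.23 (SD, n = 4) in knockout and 8.40 ± 0.24 (SD, n = 4) in wild-type samples. Its level was 3.77-fold lower (log2 difference -1.92, SE 0.19, limma adjusted p = 0.0102), in 4 of 4 knockout samples. The knockout signals, from 6.17 to 6.69, lay below the median signal of every array (6.93 to 7.42), so the size of the fall is uncertain. The difference was -2.23 in the RO samples and -1.60 in the D/F samples. In fits of 7 arrays the call was lost without wild type replicate 1 (limma adjusted p = 0.0682), 2 (0.0973) or 4 (0.0750), while the log2 difference stayed at -1.86, -1.84 and -1.92. It was also lost when only the 9969 genes of higher mean signal were tested (0.0538), and over 22 alternatives the adjusted p ran from 0.000603 to 0.0973. At least 1 gene was called in 15 of 34 splits of the 8 arrays, the genotype split included, so chance was not excluded.

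At an unadjusted limma p under 0.05 there were 449 genes, 342 lower and 107 higher in knockout samples, where 996.85 would be expected with no difference in any gene. That count depended on the arrays used: it was 4863 without wild type replicate 4 and 257 to 607 without each of the others in turn (257 without knockout replicate 2 and 291 without wild type replicate 1). It was 3203 with array weights, 2450 in the RO samples alone, 757 in the D/F samples alone and 677 after quantile normalization. The groups did not overlap for 205 genes with all knockout samples lower and for 53 with all knockout samples higher, while chance gives 569.63 such genes (2.86%). The genes of smallest p after Pja1 and Jun among those lower in both naming schemes did not pass the adjustment. Slc35f2, a solute carrier, had a log2 difference of -1.70 (SE 0.29). Map2, a microtubule-associated protein, had -1.34 (SE 0.26), Frmd4b -0.99 (SE 0.18) and Mdfi, an inhibitor of MyoD family proteins, -0.83 (SE 0.17). In the other direction, and also without passing, Apbb2 had 1.38 (SE 0.38), Gnpda2, a glucosamine-6-phosphate deaminase, 1.27 (SE 0.27), the deubiquitinase gene Uchl1 1.24 (SE 0.38) and the transcription factor gene Osr2 1.05 (SE 0.23). Ano10 had 0.76 (SE 0.23) and the pyruvate dehydrogenase kinase gene Pdk3 0.59 (SE 0.18). All 4 knockout samples lay beyond all 4 wild-type samples for Slc35f2, Frmd4b, Map2, Mdfi, Osr2 and Pdk3, but not for Gnpda2, Apbb2, Uchl1 and Ano10. The difference was 0.37 in RO and 2.40 in D/F samples for Apbb2, 0.33 and 2.15 for Uchl1, 0.68 and 1.86 for Gnpda2, -1.02 and -2.39 for Slc35f2 and -1.86 and -0.81 for Map2. These 5 were among 16 of the 116 named genes with an unadjusted interaction p under 0.05 between genotype and naming scheme, of which 0 passed the adjustment over all genes. Of the 16, Pole2, Mbd2, H2-Aa, Gata1, Msmo1 and Uty, given with their lists, had opposite signs in the 2 schemes. With 1 array left out, the difference of 80 of the 116 moved by over 1.5 times or changed sign.

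Gene lists fixed in advance were then compared between genotypes. Over all genes tested, 0 members of any list passed. Adjusted over the list alone, Jun passed in the AP-1 list and Cdk6 in the G1 list, and 0 members passed in the other lists. The median log2 difference of all 19937 genes was -0.113, so a list's median is given with that shift included. It became 0.0404 when each array was centred on its median and -0.0239 after quantile normalization. With camera at a preset inter-gene correlation, 8 of 26 lists passed relative to all other genes, 7 upward and 1 downward, and 0 of these passed with an estimated correlation or with fry. After quantile normalization 2 of the 8 passed, the interferon response (camera adjusted p = 0.00348) and the histone genes (0.0205), and the other 6 had adjusted p-values from 0.267 to 0.917.

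Genes of the early B-cell programme were higher relative to other genes (camera adjusted p = 1.8e-05), with 23 of 26 measured members higher on average in knockout samples and a median of 0.105. The adjusted p was 0.160 with an estimated correlation, and 0.110 with the preset one without wild type replicate 1. Relative to all genes the median was 0.406 in the RO samples and 0.0267 in the D/F samples, where the list did not pass (0.795). Without wild type replicates 1 and 3 it was -0.0144, although camera still pointed upward (0.708), and whether the shift of any list differed between naming schemes was not tested. Members did not pass singly: Dntt, the terminal transferase of V(D)J recombination, had a log2 difference of 1.20 (SE 0.61; 0.53 without knockout replicate 1 and 1.84 without knockout replicate 2), Rag2 0.82 (SE 0.63; 0.13 without wild type replicate 1 and 1.55 without wild type replicate 3) and Bach2 0.18 (SE 0.14), while Igll1, part of the surrogate light chain, had -0.12 (SE 0.10), which turned to 0.030 with arrays centred on their medians. Markers of mature B cells and plasma cells did not pass (camera adjusted p = 0.170). Their median was at percentile 5.5 of random lists matched on signal, and 19 of 21 were lower on average. Of these, Sdc1 had -0.63 (SE 0.26), Cd74 -0.90 (SE 0.46), H2-Aa -0.63 (SE 0.36) and Jchain -0.69 (SE 0.40). H2-Aa was at -1.63 in the RO samples and 0.36 in the D/F samples (limma interaction adjusted p = 0.535), and without wild type replicate 1 Cd74 had -0.38, H2-Aa -0.23 and Jchain -0.35.

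The interferon response list was lower relative to other genes (camera adjusted p = 0.00122), with 28 of 29 measured members lower on average and a median of -0.265. Its adjusted p was 0.689 with an estimated correlation, and 0.0885 with the preset one without wild type replicate 1. The list did not pass in the D/F samples alone (0.540), with array weights (0.0679) or without wild type replicates 1 and 3 (0.205), where its medians relative to all genes were -0.101, -0.0583 and -0.0587. Irf9, a subunit of the interferon-activated factor ISGF3, had -0.56 (SE 0.27), the deISGylase gene Usp18 -0.45 (SE 0.22), the chemokine gene Cxcl10 -0.41 (SE 0.19) and the immunoproteasome subunit Psmb9 -0.40 (SE 0.14). The wild-type Usp18 mean includes 8.23 in replicate 1, against 7.32 to 7.47 in the others.

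Other lists passed upward with camera. Oxidative phosphorylation genes had a median of 0.0638 with 21 of 29 higher (camera adjusted p = 1.8e-05; adjusted p = 0.160 with an estimated correlation), and Cox7a2, a cytochrome c oxidase subunit, had 0.39 (SE 0.15), Uqcrb 0.31 (SE 0.15), Cox6c 0.31 (SE 0.18) and Ndufb5 0.19 (SE 0.13). Other probe sets had 0.26 and 0.12 for Uqcrb and 0.25 for Cox6c. Relative to all genes the median of this list was 0.177, with 0.297 in the RO and 0.0701 in the D/F samples, both of which passed. With 1 array left out it ran from 0.0971 (without wild type replicate 1) to 0.292 (without wild type replicate 4). Without wild type replicates 1 and 3 it was 0.0304 and the call was lost (0.178). DNA replication genes had a median of 0.0675 with 21 of 31 higher (camera adjusted p = 0.000105; adjusted p = 0.572 with an estimated correlation). Of its members, the primase gene Prim1 had 0.33 (SE 0.18) and Gins1 0.27 (SE 0.17), while the polymerase subunits Pole2 and Pold2 had -0.55 (SE 0.29) and -0.19 (SE 0.13). Without wild type replicate 1 the adjusted p of this list was 0.542. Relative to all genes its median was 0.388 in the RO samples but -0.0360 in the D/F samples (0.550) and -0.0249 without wild type replicates 1 and 3 (0.849), where camera pointed downward. Histone genes had a median of 0.0904 with 9 of 12 higher (camera adjusted p = 0.000105; adjusted p = 0.508 with an estimated correlation). Their leading members were H2ac4 at 0.39 (SE 0.13), H2az1 at 0.22 (SE 0.12), H4c3 at 0.18 (SE 0.12) and H2bc3 at 0.12 (SE 0.12), and the adjusted p of the list was 0.0683 without wild type replicate 3, 0.490 in the RO samples alone and 2.21e-09 in the D/F samples alone. A second H2az1 probe set had 0.14.

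The list of mainly nucleolar and ribosome-biogenesis genes that respond to Myc had a median of 0.0103, with 13 of 25 higher (camera adjusted p = 0.00744, and 0.572 with an estimated correlation). Its members Tfb2m and Odc1, which are not nucleolar genes, had 0.32 (SE 0.15) and 0.17 (SE 0.12). Npm1 had 0.36 (SE 0.17) and Bop1 -0.24 (SE 0.15). Second probe sets had 0.17 for Tfb2m and 0.05 for Odc1. Without knockout replicate 4 the adjusted p of this list was 0.110, and without wild type replicate 3 it was 0.580. Relative to all genes its median was 0.123 with all arrays. With 1 array left out the relative median ran from 0.0370 (without wild type replicate 3) to 0.246 (without wild type replicate 4). Cholesterol and fatty-acid synthesis genes also passed upward (camera adjusted p = 0.00744; adjusted p = 0.572 with an estimated correlation), although their median was -0.00631 and their mean 0.0230, with 13 of 27 higher. The sterol enzymes Nsdhl, Msmo1 and Idi1 had 0.47 (SE 0.21), 0.35 (SE 0.22) and 0.33 (SE 0.19), and the desaturase Fads2 had -0.93 (SE 0.53), or -0.21 without knockout replicate 2; a second Idi1 probe set had -0.05. Relative to all genes the list passed upward in the RO samples (median 0.378, adjusted p = 2.03e-06) and downward in the D/F samples (-0.0865, 0.0135). The call was lost without knockout replicate 1 (0.401), wild type replicate 1 (0.0885) or wild type replicate 2 (0.206). Relative to all genes the median of this list was 0.106 with all arrays. With 1 array left out it ran from 0.0676 (without wild type replicate 1) to 0.207 (without wild type replicate 4). Genes of the integrated stress and unfolded protein response had a median of 0.00968 with 14 of 26 higher (camera adjusted p = 0.0252; adjusted p = 0.272 with an estimated correlation). Its members Psat1 and Hsp90b1 had 0.32 (SE 0.20) and 0.34 (SE 0.27), and Vldlr and Slc7a11 had -0.30 (SE 0.20) and -0.22 (SE 0.17). The call of this list was lost without knockout replicates 1 (0.114), 2 (0.0533) or 4 (0.218) and without wild type replicates 2 (0.206) or 3 (0.175). Relative to all genes its median was 0.122 with all arrays, 0.131 without knockout replicate 1 and 0.0201 without wild type replicate 2. Not every lost call thus went with a smaller shift.

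**Figure D2:**
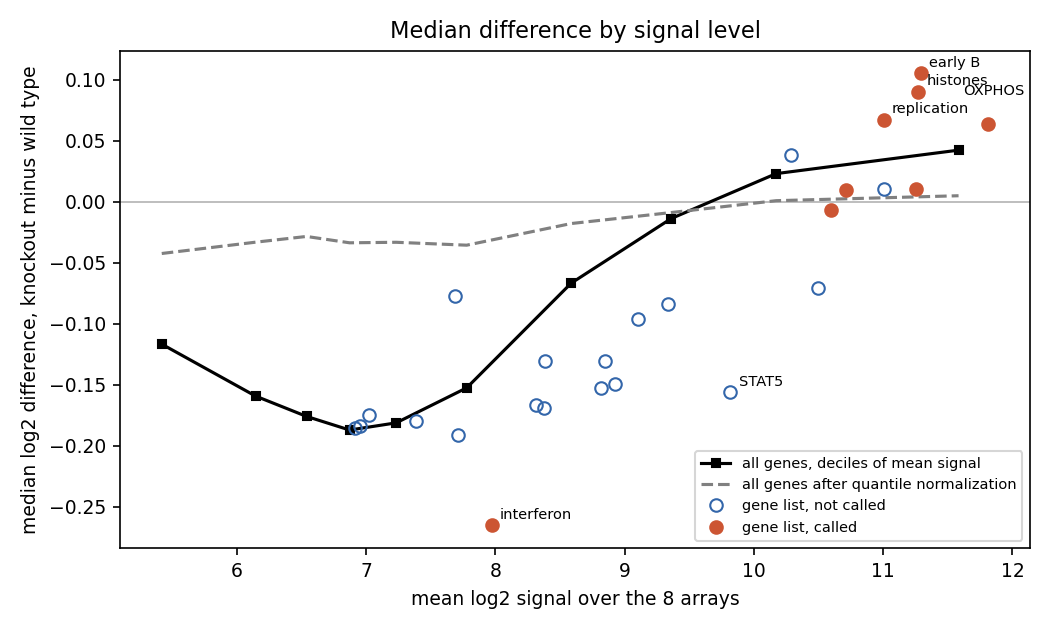
Median log2 difference, knockout minus wild type (vertical axis), against mean log2 signal over the 8 arrays (horizontal axis), for all genes in deciles of mean signal (squares), for all genes after quantile normalization (dashed line) and for the gene lists (circles, filled where camera passed). The decile medians run from -0.187 in decile 4 to 0.0425 in decile 10, and 7 of the 8 filled circles lie at high signal.

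The other lists did not pass. Among G1 cyclins, kinases and inhibitors (camera adjusted p = 0.176) Cdk6 was followed by Cdkn2a, which encodes the cell-cycle inhibitors INK4A and ARF, with a log2 difference of -1.58 (SE 0.46), which was -0.99 without wild type replicate 1 and -2.13 without wild type replicate 2. Its signals in wild-type samples were 10.97, 8.13, 9.50 and 9.49, and in knockout samples 7.93, 7.83, 8.38 and 7.65. Cyclin E2 (Ccne2) had 0.54 (SE 0.31) and E2f3 0.23 (SE 0.16). The median of this list was 0.0382, and its mean, which Cdk6 and Cdkn2a lower, was -0.129. In the AP-1 family (adjusted p = 0.176) Jun stood apart from Batf at -0.42 (SE 0.29), Fosl2 at -0.31 (SE 0.20) and Atf2 at 0.24 (SE 0.19). Described AP-1 target genes (0.293) included, besides Cdkn2a, Csf1 at -0.41 (SE 0.22), Mmp13 at -0.39 (SE 0.20) and Il2 at -0.30 (SE 0.18), with 23 of 29 members lower on average. The median of these targets, -0.166, was at percentile 3.01 of random lists matched on signal. It lay inside their central range of -0.169 to -0.0201. DNA methylation genes (0.320) had Gadd45b at -0.31 (SE 0.26), Mbd2 at 0.22 (SE 0.20), and the methyltransferases Dnmt3b and Dnmt3a at -0.21 (SE 0.17) and -0.16 (SE 0.15).

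Of genes that respond to JAK-STAT5 signalling (camera adjusted p = 0.282), 16 of 19 were lower on average. The interleukin-2 receptor chain Il2ra had -1.94 (SE 0.78), or -1.24 without wild type replicate 3. Socs3 had -0.56 (SE 0.25), or -0.28 without wild type replicate 1, and a second Socs3 probe set had -0.12. Other members were Cish at -0.36 (SE 0.21) and Mcl1 at 0.24 (SE 0.14). Apoptosis regulators (0.520) had 18 of 27 lower, among them the death receptor Tnfrsf10b at -0.87 (SE 0.23), Bmf at -0.61 (SE 0.22), Bcl2 at -0.59 (SE 0.28) and Pmaip1 at -0.52 (SE 0.22). The p53 target list (0.461) shares Tnfrsf10b and Pmaip1 with it and also held Ercc5 at -0.39 (SE 0.21) and Bbc3 at -0.38 (SE 0.22). Immediate-early and MAPK feedback genes (0.293) had Ier5 at -0.40 (SE 0.17), Spry1 at -0.39 (SE 0.18), Klf2 at -0.38 (SE 0.23) and Egr2 at -0.35 (SE 0.19). Mitosis genes (0.0637) had Nek2 at -0.31 (SE 0.24), Cdc25b at -0.29 (SE 0.16), Espl1 at -0.16 (SE 0.14) and Ube2c at -0.15 (SE 0.14), the last of which became 0.000331 with arrays centred on their medians. Glycolysis and hypoxia genes (0.282) had Egln3 at -1.14 (SE 0.34), Car9 at -0.33 (SE 0.20), Bnip3 at 0.29 (SE 0.19) and Higd1a at 0.23 (SE 0.16). Second probe sets had 0.355 for Bnip3 and 0.15 for Higd1a. Adhesion and migration genes, whose median was -0.131 while camera pointed upward (0.396), had Ccr7 at -0.85 (SE 0.47), S1pr1 at 0.57 (SE 0.27), Rhoh at 0.36 (SE 0.17) and Vav1 at -0.26 (SE 0.15).

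Markers of other cell types did not pass. Myeloid markers (camera adjusted p = 0.145) were lower on average in 19 of 21, with Fcgr3 at -1.01 (SE 0.49), Itgam at -0.38 (SE 0.20), Cd68 at -0.30 (SE 0.16) and Prtn3 at -0.29 (SE 0.20). T-cell and NK-cell markers (0.0917) were lower in 21 of 22, with Cd28 at -0.44 (SE 0.22), Nkg7 at -0.39 (SE 0.20), Cd3d at -0.34 (SE 0.19) and Gata3 at -0.30 (SE 0.20). Erythroid and megakaryocyte markers (0.199) were lower in 12 of 12, among them Gata1 at -0.33 (SE 0.21), Alas2 at -0.23 (SE 0.20), Ppbp at -0.21 (SE 0.20) and Epor at -0.21 (SE 0.21). Among random lists matched on signal, the medians of the myeloid, T-cell and NK-cell, and erythroid lists lay at percentiles 32.4, 27.8 and 38.5. These counts of lower members thus follow the general shift of genes at such signal levels. Stem and progenitor markers (0.50) had Tal1 at 0.27 (SE 0.27), Kit at -0.21 (SE 0.20), Mycn at -0.21 (SE 0.21) and Gata2 at -0.19 (SE 0.17). Stromal markers (0.283) had Fn1 at 0.98 (SE 0.74; 0.28 without knockout replicate 3 and 1.68 without knockout replicate 1), Tagln at -0.33 (SE 0.20), Pdgfrb at -0.27 (SE 0.21) and Col3a1 at -0.27 (SE 0.20). MHC genes and strain-variable class I genes (0.929) had H2-Q4 at -0.31 (SE 0.21), H2-M3 at -0.28 (SE 0.20), H2-Q2 at -0.22 (SE 0.20) and H2-T10 at -0.15 (SE 0.13), which turned to 0.00411 with arrays centred on their medians.

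Sex-linked transcripts differed between samples of 1 genotype. Xist, the RNA of the inactive X chromosome, was at 11.67, 5.90, 11.74 and 6.00 in knockout replicates 1 to 4 and at 6.16, 5.94, 11.16 and 11.93 in wild-type replicates 1 to 4. The Y-linked gene Eif2s3y was at 9.40 in knockout replicate 2 and at 9.29 and 10.22 in wild-type replicates 1 and 2, against 4.88 to 5.30 in the remaining samples. Uty and Kdm5d were likewise highest in those 3 samples. Knockout replicate 4 was low for Xist, with Uty at 5.85 and Kdm5d at 6.12. Both genotypes thus held samples with high Y-linked transcripts and samples with high Xist, which argues against 1 source for all samples of a genotype. Which samples share a source is not known. The 4 measured genes of this list were too few for camera, and their log2 differences between genotypes were 0.03 (SE 1.45) for Xist, -1.21 (SE 0.80) for Eif2s3y, -0.54 (SE 0.41) for Uty and -0.53 (SE 0.47) for Kdm5d.

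The naming schemes were compared next, because they could mark separate batches. High Y-linked transcripts occurred only in RO samples (knockout replicate 2 and wild type replicates 1 and 2), so the schemes were partly confounded with cell sex. With genotype in the limma fit, 4 genes differed, all lower in the D/F samples, and 622 had an unadjusted p under 0.05. Ralgps2, a guanine nucleotide exchange factor for Ral, had a log2 difference of -2.20 (SE 0.24, limma adjusted p = 0.0295), and the matricellular protein gene Ccn3 had -2.68 (SE 0.35, limma adjusted p = 0.0350). The olfactory receptor genes Olfr373 and Olfr372 had -1.62 (SE 0.20) and -1.65 (SE 0.21). These 4 genes are named because the count is small, after their values were seen. The count moved with each array left out, from 0 without wild type replicate 2 or 4 and 1 without knockout replicate 3 to 7, 12 and 18 without knockout replicates 4, 1 and 2 and 10 and 14 without wild type replicates 1 and 3.

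The genotype difference itself differed between the naming schemes for 6 genes (limma interaction term). Each combination of genotype and scheme held 2 samples, which may share a source. A difference between sources therefore cannot be told apart from an effect of genotype that depends on the scheme. At an unadjusted interaction p under 0.05 there were 1073 genes, where 996.85 would be expected with no interaction in any gene. The 6 genes too are named because they are few, after their values were seen. Pcbd1, a pterin-4a-carbinolamine dehydratase, was lower in the knockout RO samples by a log2 difference of -3.67 and higher in the knockout D/F samples by 3.24 (interaction adjusted p = 0.00634). The nucleotide-sugar receptor gene P2ry14 had -3.08 and 2.19, and the calcium-binding protein gene S100a11 -2.04 and 0.80. Emb, which encodes the adhesion protein embigin, had -4.08 in RO and -0.24 in D/F samples, and the aspartic protease gene Ctse had -3.85 and -0.21. Zfp938 had 0.51 and -2.77. The count of genes was 38 without wild type replicate 2, 11 without wild type replicate 4, 13 without knockout replicate 1 or 2 and 19 without knockout replicate 3 or 4. It fell to 2 after quantile normalization, 3 with 13292 genes kept and 0 with 9969 genes kept.

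**Figure D3:**
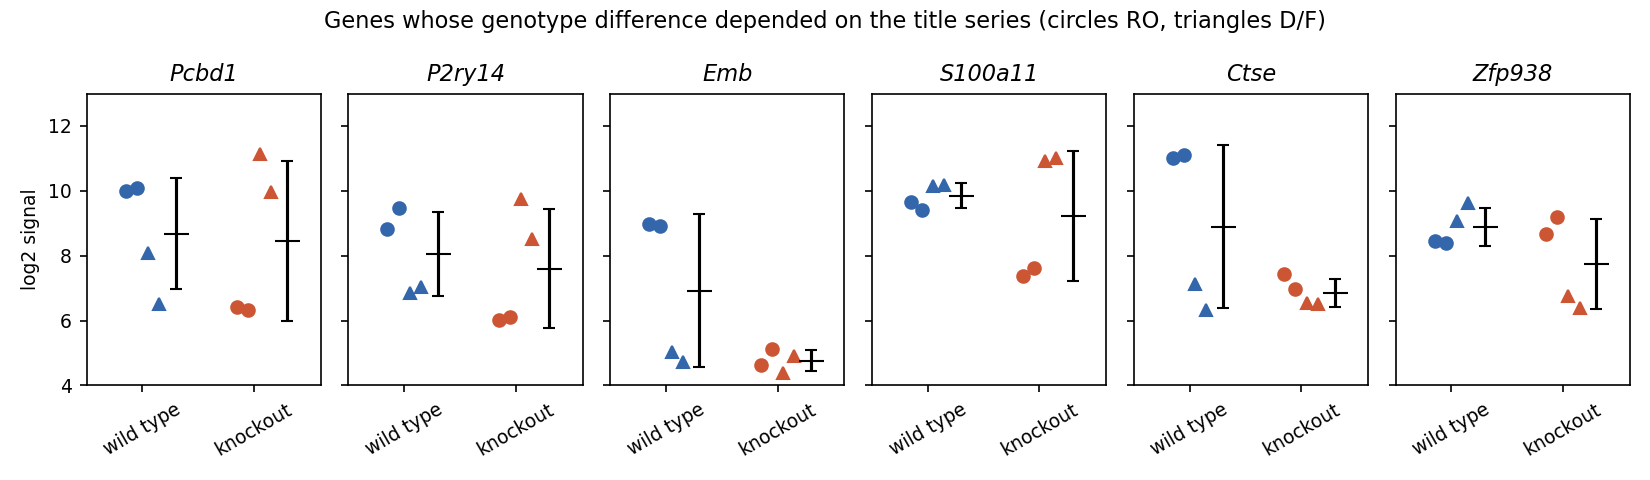
Log2 signal of the 6 genes with an interaction between genotype and naming scheme (vertical axis), by genotype (horizontal axis); circles are RO samples, triangles D/F samples, and bars show the mean ± SD of the 4 samples of a genotype. For Pcbd1 the RO knockout samples, at 6.41 and 6.32, lie below the RO wild-type samples, and the D/F knockout samples, at 11.13 and 9.95, lie above the D/F wild-type samples.

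Fitted within each naming scheme, 2 samples against 2, limma gave 25 lower and 7 higher genes in RO and 52 lower and 27 higher genes in D/F. Jun and Pja1 were the 2 genes lower in both, where 0.0652 would be shared by independent lists (Fisher's exact test, p = 0.00193), and 0 were higher in both. More genes, P2ry14, Pcbd1 and S100a11, were called in opposite directions, lower in RO and higher in D/F, where 0.0339 would be shared by independent lists (Fisher's exact test, p = 4.99e-06). Both overlaps thus exceeded that of independent lists. Fisher's test treats genes as independent and equally likely to be called, so neither p-value ties an overlap to genotype. Of the 32 genes called in RO, 12 had a difference of the same sign in D/F, and of the 79 called in D/F, 33 had the same sign in RO. The Pearson correlation of the differences, across genes and with no array in common, was -0.155; genes are not independent replicates. Pairing the 4 RO samples without regard to genotype called 88 and 103 genes, more than the 32 called between genotypes. In D/F the other pairings called 76 and 20 genes.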

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

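In 240 sets of 4 samples, the 116 named genes and 4 array-wide measures in each genotype, 15 held 1 sample far from the other 3, where chance gives about 12. The count therefore shows no excess of such samples. Among knockout samples, replicate 2 had Jun at 6.46 (the others 6.97 to 7.02), Fads2 at 8.28 (11.12 to 11.42), and the Y-linked genes Eif2s3y at 9.40 (4.89 to 5.30), Uty at 7.71 (5.63 to 5.85) and Kdm5d at 8.19 (6.05 to 6.29). Knockout replicate 1 had Pold2 at 12.29 (11.98 to 12.01), Ier5 at 8.58 (8.23 to 8.24), Cd68 at 6.98 (7.28 to 7.31), Tnfrsf10b at 6.11 (6.43 to 6.50) and H2bc3 at 13.05 (13.23 to 13.25). Knockout replicate 4 had Pdk3 at 10.70 (10.98 to 10.99). Among wild-type samples, replicate 3 had Jun at 10.55 (8.77 to 8.84), replicate 2 had Fn1 at 9.34 (6.85 to 7.27), and replicate 1 had Usp18 at 8.23 (7.32 to 7.47) and Ndufb5 at 11.42 (11.83 to 11.84).

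For the 6 interaction genes, the genotype difference in D/F minus that in RO was 6.91 (Pcbd1), 5.27 (P2ry14), 3.84 (Emb), 3.64 (Ctse), 2.84 (S100a11) and -3.28 (Zfp938) on the log2 scale, by limma's interaction term.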

How the results depend on the processing

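The fits without the 2 arrays of highest median signal (wild type replicates 1 and 3) and with Xist as a covariate were chosen after the data were seen. Jun and Cdk6 were lower in knockout samples, with an unadjusted limma p under 0.05, in all 22 alternatives: from -2.71 to -1.94 for Jun and from -3.09 to -1.70 for Cdk6. Their adjusted p over all genes was under 0.05 in 6 and 2 of the 22. Pja1 lay between -2.23 and -1.60 and passed in 18 of 22. The number of lower genes was 1, but 0 among the 9969 genes of higher mean signal, 2 with array weights, 2 without the 2 high-median arrays, 4 with Xist, and 0 to 2 with 1 array left out. The number of higher genes stayed 0 except for 2 without the 2 high-median arrays. RO alone gave 25 lower and 7 higher, and D/F alone 52 and 27.

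The number of lists called, 8, became 2 after quantile normalization, 5 with 13292 genes kept, 4 with 9969 genes kept, 0 with an estimated correlation, 0 with fry, 5 without the 2 high-median arrays, and 5 to 14 with 1 array left out (5 without wild type replicate 1 or 3, 14 without wild type replicate 4). In D/F alone 2 lists turned downward, DNA replication (median relative to all genes -0.0360) and cholesterol (-0.0865, camera adjusted p = 0.0135, against 2.03e-06 to 0.877 over its 23 alternatives). Without the 2 high-median arrays DNA replication turned to -0.0249, and camera's direction for the Myc list turned down at a relative median of 0.00573. Other totals hid lost calls, given here with camera's adjusted p: cholesterol (0.0661) and stress (0.226) after centring on medians, where 6 passed, interferon (0.0679) with array weights, where 11 passed, and Myc (0.156) and histones (0.490) in RO alone, where 10 passed. In D/F alone 8 passed, but DNA replication (0.550), early B (0.795), stress (0.151) and interferon (0.540) were lost. Without the 2 high-median arrays DNA replication (0.849), Myc (0.975), early B (0.708), stress (0.178), interferon (0.205) and oxidative phosphorylation (0.178) were lost. With 13292 genes kept Myc, cholesterol and stress were lost (0.0801 each), and with 9969 Myc, cholesterol and stress (0.332 each) and DNA replication (0.0610). Over 23 alternatives a list passed in its original direction in 19 (histones, adjusted p from 2.21e-09 to 0.678), 19 (oxidative phosphorylation, 8.96e-06 to 0.461), 17 (early B, 1.64e-07 to 0.795), 17 (interferon, 0.000336 to 0.689), 16 (DNA replication, 2.09e-06 to 0.849), 14 (Myc, 5.9e-05 to 0.975), 13 (cholesterol) and 10 (stress, 0.000477 to 0.917).

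The 4 genes that differed between naming schemes became 0 with 13292 genes kept, 0 with 9969, 12 with robust priors, 20 with array weights, 12 over every probe set, 41 without the 2 high-median arrays, 7 with Xist, and 0 to 18 with 1 array left out. The 6 interaction genes became 2 after quantile normalization, 3 with 13292 genes kept, 0 with 9969, 10 with robust priors, 12 with array weights, 10 over every probe set, 1 without the 2 high-median arrays, and 6 to 38 with 1 array left out. Centring on medians turned Ube2c to 0.000331, Igll1 to 0.0302 and H2-T10 to 0.00411. With 1 array left out Tal1 ran from -0.0127 to 0.495, Uty from -0.758 to 0.0102, Kdm5d from -0.928 to 0.0532 and Xist from -1.67 to 1.72. Fewer genes or samples were tested in the filtered and left-out fits; otherwise the cause was not tested. Signal over background was not given, so a limit from dim probe sets could not be set. No paired analysis was possible because the labels carry no replicate numbers.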

Other observations

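The tests of Pja1 against Xist and of Mtap, the count near Jun without Cdkn2a, the fit with Xist as a covariate, the rescaled fits of 1 split and the random lists matched on signal were chosen after the data were seen; the estimated correlation and quantile normalization were set beforehand, but what their outcome would count for, in the lists and in Pja1 respectively, was set after it was seen. Set against 10000 random lists matched on mean signal, 2 lists that camera had not called lay low. The median of the JAK-STAT5 list, -0.156, was at percentile 0.080, with matched lists centred on -0.0126, and that of the apoptosis regulators, -0.152, was at percentile 2.26. Il2ra, the member of smallest p in the JAK-STAT5 list, was at 7.13 ± 1.10 (SD, n = 4) in knockout and 9.07 ± 1.85 (SD, n = 4) in wild-type samples. These percentiles describe these 8 arrays and treat list members as independent.

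With the Xist level as a covariate, a fit added after the data were seen, limma called 4 genes lower in knockout samples, Pja1, Cdk6, Ogfrl1 and Jun. Cdk6 then had a log2 difference of -2.49 and an adjusted p of 0.0179, against 0.000238 to 0.99995 over its 22 alternatives. In knockout replicates 1 to 4 Cdk6 was at 9.69, 8.66, 10.11 and 6.79 and Xist at 11.67, 5.90, 11.74 and 6.00.

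Of the 8 lists called by camera, 7 lay at high signal and moved upward, as all genes did between decile 4 (median -0.187) and decile 10 (0.0425). After quantile normalization the decile medians lay between -0.0423 and 0.00509 and 2 of the 8 lists were still called, and 2 of the 8, the early B-cell programme (percentile 97.8) and the interferon response (percentile 0), lay outside the central range of signal-matched lists. With an estimated correlation 0 passed. The estimate ran from 0.00031 for the stress list, below the preset 0.01, to 0.425 for the interferon list. The stress list was lost as well, so a lost call does not by itself show that members vary together. Given the quantile-normalized and signal-matched results, a shift between arrays that depends on signal, left by the authors' scaling, may account for most of these calls. Chance could not be excluded: 17 of the 34 splits of the 8 arrays gave at least the 8 lists of the genotype split, and the highest other split gave 15; for single genes 15 of 34 splits gave at least 1 gene, and the highest other gave 7.

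Of the 34 splits of the 8 arrays, 3 gave at least the 4 genes that separated RO from D/F, so chance could not be excluded. The highest other split gave 4581 genes with genotype in the fit, but 2 with the naming scheme in its place and 0 with neither. It set wild type replicates 1 and 3 and knockout replicates 3 and 4, the 4 arrays of highest median signal, against the rest, and 4306 of the genes were lower in the rest. A count that large points to a structure among the arrays; after quantile normalization, and also after centring on medians, the same split with genotype in the fit gave 1 gene, so the count depended on the scaling of the arrays.

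Pja1 lies on chromosome X, and sex of the cells was a candidate explanation, as Xist differed between samples. Xist was high in 2 samples of each genotype, and Pja1 was at 6.53 and 6.69 in the knockout samples of high Xist and 6.17 and 6.58 in those of low Xist, against 8.09 and 8.37, and 8.55 and 8.61, in the wild-type samples. With genotype and naming scheme in the fit, Pja1 changed by -0.0314 (SE 0.26) over the whole span of Xist, which argues against cell sex as read from Xist, and after quantile normalization the difference between genotypes was -1.80, which argues against a shift of the whole array. An effect of the genotype, another difference between the samples and chance remain open. Of the 34 splits of the 8 arrays, 15 gave at least 1 gene, the genotype split included. With nothing planted, 8 of 20 simulations also made a call. The call, though not the size of the difference, was lost without wild type replicate 1, 2 or 4. The log2 difference was then -1.86, -1.84 and -1.92 and the limma adjusted p 0.0682, 0.0973 and 0.0750.

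Cdkn2a lies 14 measured genes from Jun on chromosome 4, so a flanking segment carried along with the knockout allele could lower it without c-JUN. Of the 50 measured genes nearest Jun, 3 had an unadjusted p under 0.05, but that count includes Cdkn2a itself and so decides nothing. Of the other 49, 2 did, Ifna16 and Tusc1, where the share over all genes gives 1.10; the exact 95% Poisson interval of the count, 0.242 to 7.22, is too wide to exclude a flanking segment, which therefore cannot be told apart from an effect of c-JUN. Loss of the locus together with Mtap, the neighbour of Cdkn2a, is argued against by Mtap at -0.283 (SE 0.18), while Cdkn2b, at -0.15 (SE 0.39), leaves a smaller loss open. Cdkn2a did not pass the adjustment over all genes, and its difference ran from -2.13 to -0.99 with 1 array left out.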
